A study of Homo sapiens with 9 samples.

How the data were processed

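The samples were 9 cultures of H2009, a line of human lung adenocarcinoma cells, in 3 groups of 3 arrays: cells with the guide RNA sgRNA-A, cells with sgRNA-B, and control cells with an empty guide vector. Groups and replicate numbers were taken from the sample titles. Total RNA was copied into biotin-labelled RNA and hybridised to Affymetrix arrays, per the labels' protocols, which give an RNA integrity number of 10 for every sample. The array model was not used here.

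The table analysed holds 1 value per probe set and array, deposited by the authors on a log2 scale, and RMA was used to make it, per the submitters' processing notes; its version is not given in the sources used here. RMA corrects background, makes the distributions of the arrays equal and summarises the probes of a set, so shifts that move all genes of an array together are removed before any test. The values bear out a log2 scale and distributions made equal: each of the 9 columns had a median of 4.91, and they spanned 3.38 to 13.82. They are levels of single samples, not ratios, and no centring of genes was found. Background settings and the probe-to-gene definition stay unknown.

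Of 24733 probe sets, 23934 had 1 gene symbol in the annotation table supplied with the values, 0 had several and 799 had none. Each identifier is a gene number followed by _at, and 23893 of the numbers matched a record of RefSeq's annotation of assembly GRCh38.p14. That annotation was used for gene names and for the order of neighbouring genes; no coordinates are printed because the files name no genome build. For 3 symbols with more than 1 probe set, the one with the highest mean over the 9 arrays was kept, which left 23931 genes. No filter on dim genes was applied. The 799 unnamed probe sets were left out of the gene tests and fitted separately.

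All 9 arrays entered 1 linear model per gene with a mean per group, in limma 3.58.1 (R 4.3.3), with lmFit and eBayes(trend=TRUE). The fit had 6 residual and 7.27 prior degrees of freedom. The contrasts were sgRNA-A against control, sgRNA-B against control, sgRNA-A against sgRNA-B, and the mean of both guides against control. P-values were adjusted by the method of Benjamini and Hochberg over the 23931 genes, and a gene is said to have risen, fallen or changed when its adjusted p was below 0.05. Log2 fold changes are given with the standard error of the fit (SE) and group levels as mean ± SD of 3 arrays in log2 units. The labels call the arrays biological replicates of each clone; with 1 clone per guide, an effect of the guide and a property of the clone cannot be separated, and the p-values cover the spread between cultures of these clones. The number of arrays limits the precision.

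The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes the measured members of the 14q32 list; the 8 largest rises and 8 largest falls of each guide against control among changed genes whose arrays do not overlap; the 8 rises and 8 falls shared by both guides with the largest smaller change; the 5 largest differences in each direction between the guides; and up to 4 members of each list with the smallest adjusted p per contrast. The 38 lists cover the 14q32 locus and its flanks, other imprinted genes, cell identity, markers of other cell types, proliferation, stress, signalling and metabolism, and each was tested in each contrast with limma's camera at a preset correlation between genes of 0.01, adjusted over lists. The result of 1 list is not reported here. Counts of members adjusted over the list alone stand beside the counts over all genes. Camera was rerun with an estimated correlation and on ranks, and fry, which does not compare a list with other genes, was run as well. After the probe sets were seen to include small RNA genes, all 102 probe sets from DLK1 to DIO3 in RefSeq order were tested as 1 further set. The level of silent genes was taken as the 95th percentile of the means of 355 olfactory receptor genes.

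The steps were tested on simulated data with 200 of 23931 genes changed in sgRNA-A against control, over 5 simulations: 86% of genes changed by a log2 of 0.5 and 99.8% of those changed by 1 were recovered, with 5.78% false calls. A list shifted by 0.2 was recovered in 5 of 5. Genes were simulated without correlation between them, so this does not show how correlated members affect the list calls. To see what sharing control arrays produces by itself, arrays of all groups, controls included, were simulated without effects 100 times. The controls were drawn anew, so this does not show what the measured control arrays contributed. Alternatives were: leaving out each array, the replicate number as a block, array weights, robust and untrended variances, an unmoderated t statistic, fits of the compared groups alone, removal of the dimmest 30% or 50% of genes, repeated quantile normalization, median centring, other rules for several probe sets, an adjusted p of 0.01 and a 2-fold minimum. Other splits of the arrays were counted with fits of 2 groups, or of 3 for the shared calls. Neighbouring genes were tested as runs of 20 genes against 1000 shuffled orders. Plots were drawn with matplotlib 3.10.9. A planned test of the 14q32 microRNAs' seed sites needs transcript sequences, and was not analysed here.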

Results

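Expression was measured on arrays in H2009 lung adenocarcinoma cells that carry CRISPRa, a Cas9 without nuclease activity fused to transcription activators, which a guide RNA directs to a chosen site. The guides sgRNA-A and sgRNA-B were used to raise the microRNAs of the imprinted 14q32 locus, short RNAs that repress messenger RNAs with matching sites. Control cells held an empty guide vector. Each group had 3 arrays. The comparisons ask which messenger RNAs differ once these microRNAs have been raised, which the submitters measured by RT-qPCR beforehand, and whether both guides share the differences. Correlations between arrays ranged from 0.9970 to 0.9982 within groups and from 0.9958 to 0.9980 between groups. The first principal component, with 22.8% of the variance, held the control arrays at 8.86 to 13.6 and the activated arrays at -11.2 to -3.77. Replicate 3 of sgRNA-A stood apart on the second component (21.8% of the variance) at 19, and its root mean square distance from the other arrays of its group was 0.168, against 0.126 to 0.146 elsewhere.

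No probe set of the targeted locus passed the test with either guide on these arrays. DLK1, an imprinted Notch ligand homologue, measured 4.26 ± 0.04 log2 units in control cells, 4.29 ± 0.04 with sgRNA-A and 4.22 ± 0.07 with sgRNA-B. The non-coding RNA MEG3 measured 3.61, 3.55 and 3.64, MEG9 4.45, 4.54 and 4.41, and the deiodinase gene DIO3 3.99, 3.85 and 3.88. None of the 14 measured members of the fixed locus list changed with either guide in limma, and 0 had an unadjusted p below 0.05 with sgRNA-A and 0 with sgRNA-B (camera adjusted p = 0.775 and 0.819). The arrays also held 102 probe sets from DLK1 to DIO3, of which 52 are microRNA genes, 41 small nucleolar RNA genes and 9 others. Their median log2 fold change was 0.011 with sgRNA-A and -0.013 with sgRNA-B, and 0 changed in limma after Benjamini-Hochberg adjustment, with 1 and 4 at an unadjusted p below 0.05. The lowest adjusted p was 0.255 with sgRNA-A and 0.135 with sgRNA-B in limma, and camera did not call the set in either comparison. Between the guides the median was 0.015 and 0 changed in limma, with 5 at an unadjusted p below 0.05. Camera put the set below an unadjusted 0.05 there with an estimated correlation, but not with the preset one. Of the 102, 90 lay at or below 4.44 log2 units, the level below which 95% of olfactory receptor genes lay, and their median level was 3.68 against 4.89 for all genes. The other 1302 small RNA probe sets had a median level of 3.95.

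**Figure D1:**
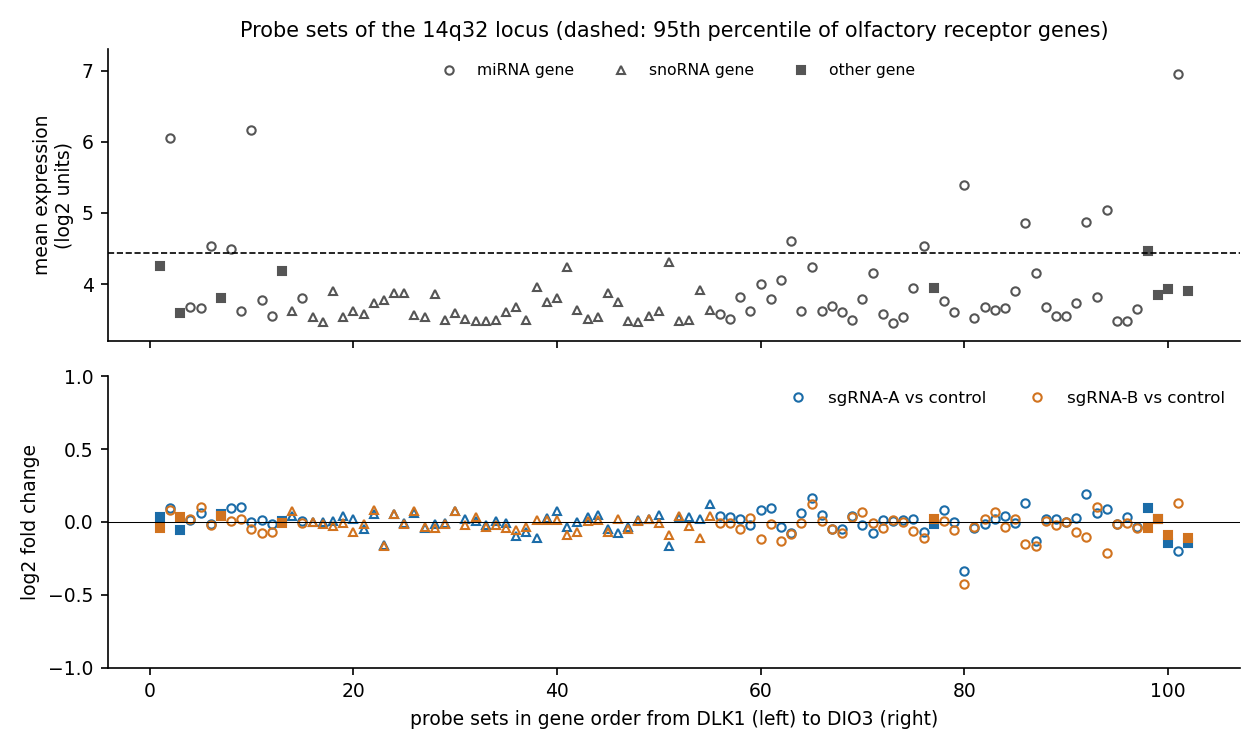
Mean expression over 9 arrays (upper panel, log2 units) and log2 fold change of each guide against control (lower panel) for the 102 probe sets from DLK1 to DIO3 in gene order, with the dashed line at 4.44. Most points lie below the line, and the fold changes scatter around 0 with medians of 0.011 and -0.013.

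With sgRNA-A, the largest fall was that of CEACAM5, the carcinoembryonic antigen, from 11.05 ± 0.04 log2 units in control cells to 9.02 ± 0.09 (log2 fold change -2.03, SE 0.06; adjusted p = 7.38e-10, limma). LCN2, a secreted protein that binds iron carriers, fell from 7.99 ± 0.25 to 6.37 ± 0.35, and the membrane serine protease TMPRSS4 from 7.84 ± 0.08 to 6.22 ± 0.05. The largest rise was that of MB, the oxygen-binding protein myoglobin, from 7.21 ± 0.25 to 8.94 ± 0.07 (log2 fold change 1.73, SE 0.10; adjusted p = 1.86e-06, limma). IGFBP4, which binds insulin-like growth factors, rose from 7.76 ± 0.10 to 8.81 ± 0.04. Falls continued with the water and glycerol channel AQP3 (-1.06), the zinc finger gene ZNF605 (-1.03), the adhesion gene PCDH19 (-0.97), the lysosomal protease CTSV (-0.96) and the membrane glycoprotein GPNMB (-0.89). Rises continued with the calcium-binding S100A3 (0.94), the protocadherin PCDHB6 (0.84), the mitochondrial arginase ARG2 (0.78), the kinase NRK (0.73), the B-cell receptor component CD79A (0.71) and the growth factor BMP4 (0.70). Without control replicate 1, AQP3 was no longer called (adjusted p = 0.0577, limma). PCDHB6 lost its call without sgRNA-A replicate 1 (0.102), sgRNA-A replicate 2 (0.102) or control replicate 1 (0.0514). BMP4 lost it when any 1 of the sgRNA-A replicates 1 to 3, sgRNA-B replicates 2 and 3 or control replicate 3 was left out, with limma's adjusted p reaching 0.112.

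G2/M and mitosis genes were higher with sgRNA-A than in control cells, relative to other genes (median log2 fold change 0.17, camera adjusted p = 7.52e-17). Of 30 members, 8 rose, 0 fell and 22 did not pass the test, 23 rose when adjusted over the list alone, and all 30 had a fold change above 0. Among them, the kinesin KIF20A rose by 0.37, and CDC20 and DLGAP5, which act in mitosis, each by 0.24. Epithelial genes were lower (29 members, median -0.13, camera adjusted p = 4.03e-05): 2 fell, 0 rose and 27 did not pass the test, with 11 falls and 0 rises adjusted over the list alone. The epithelial transcription factor ELF3 fell by 0.35 and the keratin KRT7 by 0.18, though KRT7 was not called without sgRNA-A replicate 1 (0.0734), control replicate 1 (0.0769) or control replicate 2 (0.0512). These lists held their calls with an estimated correlation (adjusted p = 0.0327 each).

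Further lists shifted with sgRNA-A, and none of their calls held with an estimated correlation. Notch pathway genes were lower (18 members, 3 fell and 15 did not pass, median -0.12, camera adjusted p = 0.000774, and adjusted p = 0.0620 with an estimated correlation), with 4 falls adjusted over the list alone. The receptor NOTCH3 fell by 0.62 and the coactivator MAML2 by 0.46. Mesenchymal genes were higher (29 members, 3 rose, 1 fell, 25 did not pass, median 0.055, camera adjusted p = 0.00501, and adjusted p = 0.112 with an estimated correlation), with 7 rises and 2 falls adjusted over the list alone. The receptor tyrosine kinase AXL rose by 0.39, while the matrix protein TNC fell by 0.22. Squamous and basal genes were lower (20 members, 1 fell and 19 did not pass, median -0.11, camera adjusted p = 0.00581, and adjusted p = 0.112 with an estimated correlation), with 1 rise and 6 falls adjusted over the list alone. The member that fell was the calcium-binding S100A2 (-0.68), which was not called without control replicate 1 (adjusted p = 0.0537, limma).

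The remaining list calls with sgRNA-A had larger camera p-values. Oxidative phosphorylation genes were higher (22 members, 2 rose and 20 did not pass, median 0.076, camera adjusted p = 0.0148, and adjusted p = 0.159 with an estimated correlation), with 3 rises and 1 fall adjusted over the list alone. Its member ATP5MC1, an ATP synthase subunit, rose by 0.58, a call lost without sgRNA-A replicate 2 (0.0702) or 3 (0.0646). Hypoxia genes were higher (26 members, 3 rose and 23 did not pass, median 0.071, camera adjusted p = 0.0325, and adjusted p = 0.159 with an estimated correlation), with 6 rises and 2 falls adjusted over the list alone; LOXL2, a lysyl oxidase, rose by 0.54. Ribosomal protein genes were higher (21 members, 2 rose and 19 did not pass, median 0.053, camera adjusted p = 0.0325, and adjusted p = 0.139 with an estimated correlation), with 3 rises and 1 fall adjusted over the list alone. Cholesterol synthesis genes were higher (19 members, 3 rose and 16 did not pass, median 0.068, camera adjusted p = 0.0389, and adjusted p = 0.186 with an estimated correlation), with 7 rises and 2 falls adjusted over the list alone; ACAT2 rose by 0.28. ERK pathway output genes were lower as a list (21 members, 2 rose, 1 fell, 18 did not pass, median -0.072, camera adjusted p = 0.0325, and adjusted p = 0.235 with an estimated correlation), with 3 rises and 5 falls adjusted over the list alone. Its phosphatase gene DUSP5 fell by 0.35, and the transcription factor genes ETV5 (0.49) and FOSL1 (0.18) rose. DNA replication genes were lower (32 members, 1 fell and 31 did not pass, median -0.054, camera adjusted p = 0.0379, and adjusted p = 0.139 with an estimated correlation), with 1 rise and 3 falls adjusted over the list alone; the helicase subunit MCM6 fell by 0.22.

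Several of these calls lay near the threshold and were lost when 1 array was left out, most of them for more than 1 choice of array. Fewer arrays stood behind each refit, so a lost call need not mean that 1 array carried the shift. Without sgRNA-A replicate 3, camera's adjusted p was 0.0729 for oxidative phosphorylation, 0.0676 for hypoxia, ribosomal protein and ERK output genes, 0.0748 for cholesterol synthesis and 0.110 for DNA replication. Without control replicate 2 it was 0.0791 for hypoxia and DNA replication, 0.0847 for ribosomal protein genes and 0.0960 for cholesterol synthesis. Without control replicate 3 it was 0.129 for cholesterol synthesis and DNA replication and 0.157 for ERK output genes. Without sgRNA-A replicate 2 it was 0.0929 for cholesterol synthesis and 0.0834 for ERK output genes, and without sgRNA-A replicate 1 it was 0.0590 for DNA replication. ETV5 was not called without sgRNA-A replicates 1, 2 or 3 or control replicates 1 or 3 (limma's adjusted p up to 0.110). FOSL1 was not called without sgRNA-A replicates 1 or 3, any sgRNA-B replicate, or control replicates 1 or 2 (up to 0.190).

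In all, limma called 522 of 23931 genes with sgRNA-A, 229 higher and 293 lower, with a median absolute log2 fold change of 0.34. Of these, 7 changed at least 2-fold (2 higher, 5 lower) and 73 at least 1.5-fold. The count was 223 without control replicate 1, 269, 321 and 254 without sgRNA-A replicates 1, 2 and 3, and lists shifted numbered 11, against 5 without sgRNA-A replicate 3 and 7 without control replicate 2.

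**Figure D2:**
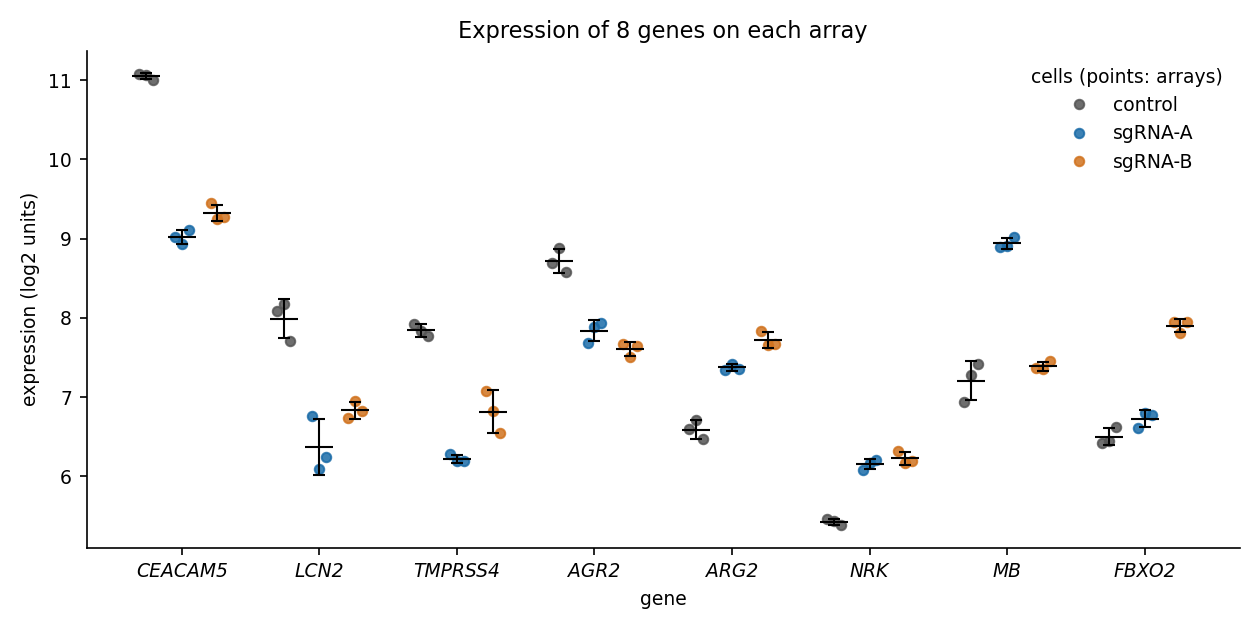
Expression (log2 units) of 8 genes on each of the 9 arrays, with points for arrays and black bars for the mean ± SD of 3. CEACAM5, LCN2, TMPRSS4 and AGR2 lie lower and ARG2 and NRK higher with both guides, MB rose with sgRNA-A (8.94 ± 0.07) and FBXO2 with sgRNA-B (7.90 ± 0.08).

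With sgRNA-B, CEACAM5 also fell most, to 9.32 ± 0.11 log2 units (log2 fold change -1.72, SE 0.06; adjusted p = 6.16e-09, limma), followed by LCN2 at 6.84 ± 0.11 (-1.16). AGR2, an endoplasmic reticulum protein that mucin folding needs, fell from 8.72 ± 0.15 to 7.61 ± 0.09 (-1.11), and TMPRSS4 to 6.82 ± 0.27 (-1.03). FBXO2, a ubiquitin ligase subunit that recognises glycoproteins, rose most, from 6.50 ± 0.11 to 7.90 ± 0.08 (log2 fold change 1.40, SE 0.09; adjusted p = 6.08e-06, limma), and ARG2 rose from 6.59 ± 0.12 to 7.72 ± 0.10 (1.13). The retinal reductase DHRS3 (0.97), BMP4 (0.96), PCDHB6 (0.96), CD79A (0.93), the caveolar protein CAVIN2 (0.92) and the interferon-induced IFIT3 (0.88) rose as well. Further falls were those of TMEM40 (-0.96), the hyaluronan-binding CEMIP (-0.92), S100A2 (-0.85) and CTSV (-0.79). PCDHB6 was not called without sgRNA-B replicate 1 (adjusted p = 0.0530, limma).

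G2/M and mitosis genes were higher with sgRNA-B too: 14 of 30 rose, 0 fell and 16 did not pass the test, 22 rose adjusted over the list alone, and all 30 had a fold change above 0 (median 0.18, camera adjusted p = 1.11e-18). KIF20A rose by 0.43, the centromere histone gene CENPA by 0.38, CDC20 by 0.32 and DLGAP5 by 0.27. Cholesterol synthesis genes were higher (19 members, 4 rose, 0 fell and 15 did not pass, median 0.20, camera adjusted p = 5.15e-07), with 13 rises and 3 falls adjusted over the list alone. The enzymes DHCR7 (0.48), ACAT2 (0.32) and SQLE (0.25) and the sterol carrier STARD4 (0.42) rose. Both lists held their calls with an estimated correlation (adjusted p = 0.0364 each).

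Interferon response genes were higher with sgRNA-B, with members moving both ways: 10 of 32 rose, 2 fell and 20 did not pass the test, and 11 rose and 3 fell adjusted over the list alone (median 0.039, mean 0.12, camera adjusted p = 0.00156, and adjusted p = 0.0994 with an estimated correlation). IFIT3 (0.88), IFI44 (0.52), ISG15 (0.42) and HERC6 (0.40) rose, while OAS1, a sensor of double-stranded RNA, fell by 0.37. The interferon-induced IFI27 fell from 4.88 ± 0.18 log2 units to below the level of silent genes. With sgRNA-A the interferon list was not called (camera adjusted p = 0.775), and 1 member rose and 3 fell. The directions of the 6 genes named were not particular to sgRNA-B. All sgRNA-A arrays also lay above the control arrays for IFIT3, IFI44, ISG15 and HERC6, and below them for OAS1 and IFI27. Mucin and gastrointestinal genes were lower (22 members, 4 fell and 18 did not pass, median -0.017, mean -0.20, camera adjusted p = 0.0149, and adjusted p = 0.118 with an estimated correlation), with 1 rise and 4 falls adjusted over the list alone. The 4 members were CEACAM5, AGR2, the mucin MUC16 (-0.59) and the adhesion glycoprotein CEACAM6 (-0.54). With sgRNA-A 4 members of this list fell and 1 rose as well, though the list was not called (mean -0.16, camera adjusted p = 0.0864). Notch pathway genes were lower with sgRNA-B (18 members, 2 fell and 16 did not pass, median -0.13, camera adjusted p = 0.00694, and adjusted p = 0.101 with an estimated correlation), with 4 falls adjusted over the list alone, and the members were the ligand JAG1 (-0.50) and NOTCH3 (-0.48). Squamous and basal genes were lower (20 members, 3 fell and 17 did not pass, median -0.094, camera adjusted p = 0.0131, and adjusted p = 0.125 with an estimated correlation), with 4 falls adjusted over the list alone, S100A2 first; without sgRNA-B replicate 3 the list's adjusted p was 0.0625. IFI27 was not called without sgRNA-B replicate 1 (0.0740), sgRNA-B replicate 3 (0.0794) or control replicate 1 (0.0762). OAS1 was not called when any 1 sgRNA-B or control replicate was left out (0.0691 to 0.132), nor NOTCH3 without sgRNA-B replicates 1 or 2 or control replicates 1 or 3 (up to 0.109).

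limma called 735 genes with sgRNA-B, 374 higher and 361 lower, with a median absolute log2 fold change of 0.33; 6 changed at least 2-fold (2 higher, 4 lower) and 75 at least 1.5-fold. The count was 353, 400 and 459 without sgRNA-B replicates 1, 2 and 3, 413 without control replicate 1 and 453 without control replicate 3.

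Both guides moved the same way at 298 genes, 136 higher and 162 lower, and 0 genes changed in opposite directions. The shared falls with the largest changes were CEACAM5, LCN2, TMPRSS4, AGR2 (-0.88 with sgRNA-A), CEMIP (-0.87 with sgRNA-A), CTSV, the amino acid transporter SLC6A14 (-0.84 and -0.76) and the proline dehydrogenase PRODH (-0.88 and -0.76). The shared rises were ARG2, PCDHB6, NRK (0.73 and 0.80), CD79A, BMP4, S100A3 (0.94 and 0.70), the peroxidase GPX8 (0.60 and 0.88) and the membrane receptor ANTXR1 (0.60 and 0.62). GPX8 was not called for sgRNA-A without sgRNA-A replicates 1 or 2 or control replicates 2 or 3 (limma's adjusted p up to 0.0868). Independent lists of these sizes would share 3.58 higher and 4.42 lower genes. Simulated groups without effects, set against simulated and not the measured control arrays, shared 0 calls in 20 simulations. This weighs little, as groups without effects give few calls to share. Across genes, which are not independent replicates, the fold changes of the guides correlated at 0.60, against 0.50 in simulations without any effect, with a covariance of 0.0107 against 0.00374. The same sign was seen at 67.5% of genes against 66.7% in simulations. With 3 control arrays the controls could not be split, and part of the overlap may come from them. Leaving out control replicate 1 gave 137 shared genes and control replicate 3 gave 195; sgRNA-A replicates 1, 2 and 3 gave 177, 196 and 175, and sgRNA-B replicates 1 and 2 gave 186 and 192.

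**Figure D3:**
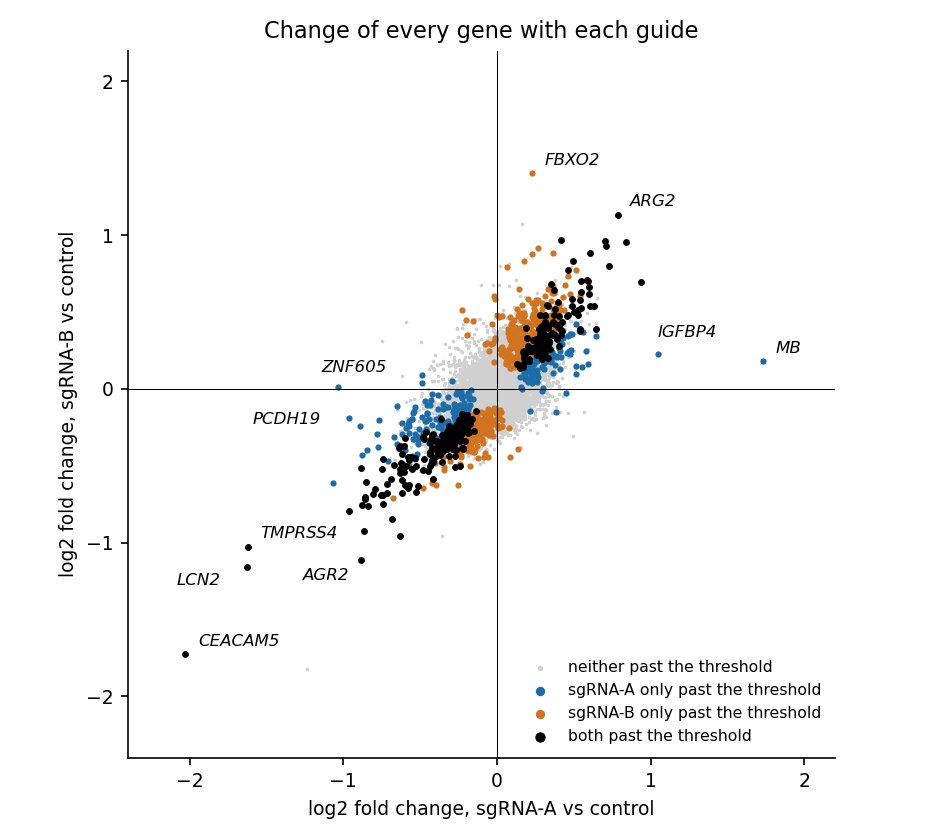
Log2 fold change of each of 23931 genes with sgRNA-A (horizontal) and sgRNA-B (vertical) against control, coloured by which comparison passed an adjusted p of 0.05. The 298 genes past it in both (black) lie in the lower left and upper right quadrants.

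Averaged over both guides, G2/M and mitosis genes stood highest (17 of 30 rose, 0 fell and 13 did not pass, 26 rose adjusted over the list alone, median 0.19, camera adjusted p = 1.26e-20, and adjusted p = 0.0311 with an estimated correlation). Cholesterol synthesis (median 0.13, camera adjusted p = 0.000101, and adjusted p = 0.0645 with an estimated correlation) and oxidative phosphorylation genes (median 0.059, camera adjusted p = 0.0188, and adjusted p = 0.185 with an estimated correlation) were higher, with 4 of 19 and 2 of 22 members rising. Lower lists were Notch pathway (4 of 18 fell, median -0.15, camera adjusted p = 0.000531, and adjusted p = 0.0645 with an estimated correlation), squamous and basal (3 of 20 fell, median -0.096, camera adjusted p = 0.00331, and adjusted p = 0.0864 with an estimated correlation) and epithelial genes (3 of 29 fell, median -0.078, camera adjusted p = 0.00419, and adjusted p = 0.0751 with an estimated correlation). ERK output genes (2 of 21 rose and 4 fell, median -0.058, camera adjusted p = 0.0352, and adjusted p = 0.210 with an estimated correlation) and DNA replication genes (1 of 32 rose and 3 fell, median -0.031, camera adjusted p = 0.0396, and adjusted p = 0.140 with an estimated correlation) were lower as lists. Mucin and gastrointestinal genes were lower too (1 of 22 rose and 4 fell, median -0.011, camera adjusted p = 0.0352, and adjusted p = 0.140 with an estimated correlation). Several of these lists were called with 1 guide only. With sgRNA-B camera's adjusted p was 0.269 for epithelial, 0.112 for DNA replication, 0.0803 for oxidative phosphorylation and 0.0779 for ERK output genes. With sgRNA-A it was 0.0864 for mucin and gastrointestinal genes. For the mean of both guides limma called 855 genes, 424 higher and 431 lower, 405 without control replicate 1 and 496 without control replicate 3. Of the 9 lists, 5 were called without control replicate 3, where camera's adjusted p was 0.154 for ERK output, 0.0948 for DNA replication, 0.0832 for mucin and gastrointestinal and 0.0620 for oxidative phosphorylation genes. Without sgRNA-A replicate 3 it was 0.0756 for DNA replication, 0.0557 for oxidative phosphorylation and 0.0535 for mucin and gastrointestinal genes. DNA replication genes were also not called without sgRNA-B replicate 3 (0.0714) or control replicate 2 (0.0827), and ERK output genes without sgRNA-B replicate 2 (0.0610).

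**Figure D4:**
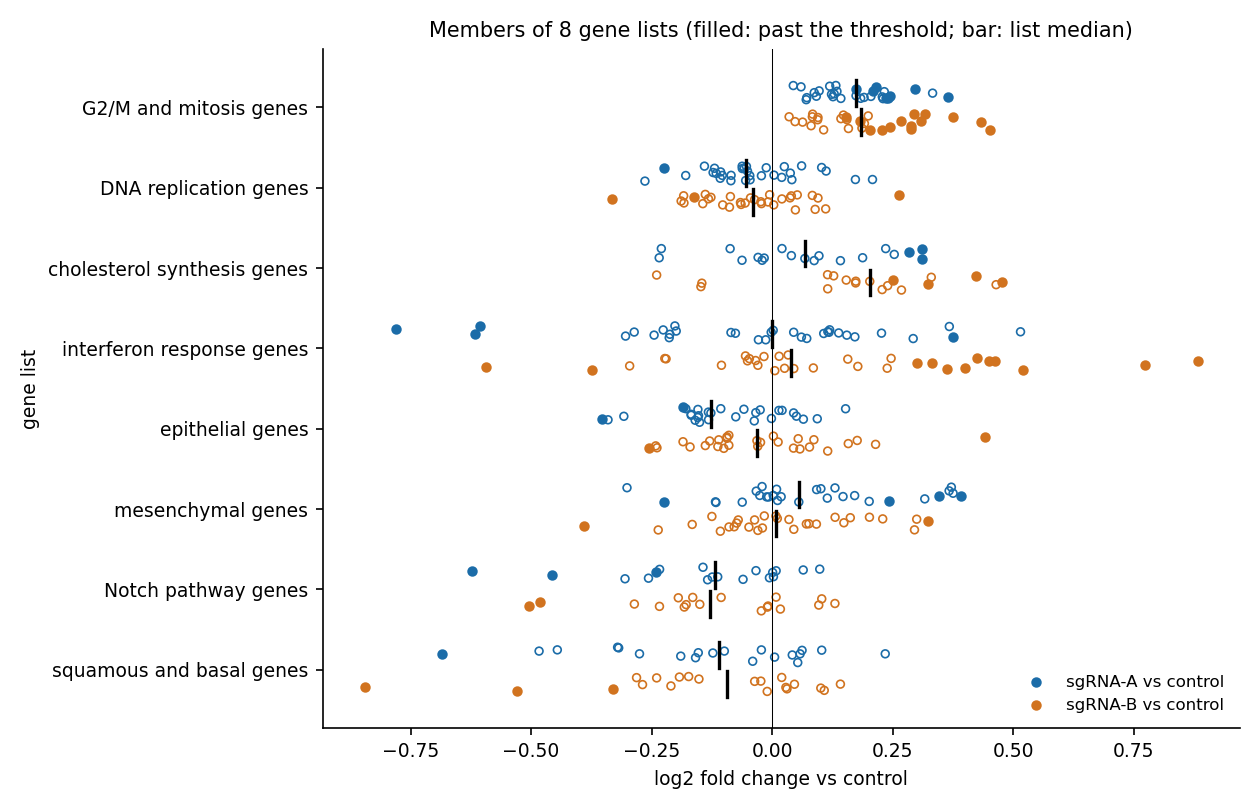
Log2 fold change against control of each member of 8 gene lists, with sgRNA-A in blue and sgRNA-B in orange, filled where the adjusted p was below 0.05, and a bar at the list median. All 30 G2/M and mitosis genes lie above 0 with both guides, at medians of 0.17 and 0.18, and DNA replication genes lie on both sides of 0.

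The direct comparison of the guides found few genes. MB was higher with sgRNA-A than with sgRNA-B (8.94 ± 0.07 against 7.39 ± 0.06 log2 units; log2 fold change 1.55, SE 0.10; adjusted p = 2.25e-05, limma), as were IGFBP4 (0.82), the calcium-binding S100A4 (0.55), the heme-degrading enzyme HMOX1 (0.47) and FAM133B, whose mean with sgRNA-B lay below the level of silent genes. FBXO2 was lower with sgRNA-A (6.73 ± 0.11 against 7.90 ± 0.08; log2 fold change -1.17, SE 0.09; adjusted p = 8.35e-05, limma), as were ZNF605 (-1.05), PCDH19 (-0.77), the annexin ANXA9 (-0.74) and the helicase DDX60 (-0.65), which interferon induces. limma called 25 genes, 10 higher and 15 lower with sgRNA-A, 3 of them at least 2-fold, and 2511 genes had an unadjusted p below 0.05. Of the 959 genes called against control with either guide, 24 differed between the guides. An unmoderated t statistic called 0 genes here, with 2287 at an unadjusted p below 0.05. The count was 9, 8 and 11 without sgRNA-A replicates 1, 2 and 3, and 6, 8 and 12 without sgRNA-B replicates 1, 2 and 3. MB, IGFBP4, HMOX1, FBXO2 and PCDH19 held their calls without any 1 array, whereas ZNF605, S100A4 and FAM133B lost theirs when any 1 array of either guide was left out (limma's adjusted p 0.0601 to 0.188). ANXA9 also lost it without control replicate 1 (0.0620), and DDX60 without sgRNA-A replicates 1 or 3 or any sgRNA-B replicate (0.0623 to 0.0896).

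Interferon response genes were lower with sgRNA-A than with sgRNA-B (32 members, 1 fell and 31 did not pass, median -0.14, camera adjusted p = 3.59e-08), with 9 falls adjusted over the list alone, and this call held with an estimated correlation (adjusted p = 0.0298). The mean of the list was 6.54 to 6.58 log2 units on the sgRNA-B arrays, 6.37 to 6.43 on the sgRNA-A arrays and 6.41 to 6.46 on the control arrays. Cholesterol synthesis genes were lower with sgRNA-A (19 members, 0 past the threshold, median -0.095, camera adjusted p = 0.000319, and adjusted p = 0.125 with an estimated correlation). Epithelial genes were lower with sgRNA-A (29 members, 1 fell and 28 did not pass, median -0.069, camera adjusted p = 0.00958, and adjusted p = 0.125 with an estimated correlation), with 5 falls adjusted over the list alone; the member was the tight junction gene TJP3 (-0.60). Mesenchymal genes were higher (29 members, 1 rose and 28 did not pass, median 0.068, camera adjusted p = 0.00958, and adjusted p = 0.166 with an estimated correlation), with 4 rises adjusted over the list alone, S100A4 among them. The epithelial call was lost without sgRNA-B replicate 1 (0.0617) and the mesenchymal call without sgRNA-A replicate 1 (0.103). Of the genes, S100A4 was not called when any 1 array of either guide was left out (limma's adjusted p 0.0681 to 0.153), nor was TJP3 (0.0720 to 0.184).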

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

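The test of the locus against silent genes, the look at its probe sets above that level, the test of cycling cells, and, for neighbouring genes, the tests without the most changed gene and with gene families averaged were chosen after the results were seen; the remaining tests were set before.

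The guides differed from each other, by limma's test of that difference, at 25 genes, and the following log2 differences are sgRNA-A minus sgRNA-B. Higher with sgRNA-A were MB (1.55), IGFBP4 (0.82), S100A4 (0.55), FAM133B (0.53), HMOX1 (0.47), the hypoxia gene NDRG1 (0.36), the receptor TGFBR1 (0.33) and the laminin LAMB3 (0.32). Lower with sgRNA-A were FBXO2 (-1.17), ZNF605 (-1.05), PCDH19 (-0.77), ANXA9 (-0.74), CAVIN2 (-0.65), DDX60 (-0.65), TJP3 (-0.60), DHRS3 (-0.55), the mucin MUC1 (-0.45) and the serine synthesis enzyme PHGDH (-0.31). Of these 18 genes, 6 kept their calls without any 1 array: MB, IGFBP4, PCDH19, FBXO2, CAVIN2 and HMOX1. The list medians that differed were those of interferon response genes (-0.14), cholesterol synthesis genes (-0.095), epithelial genes (-0.069) and mesenchymal genes (0.068), of which only the interferon call held with an estimated correlation. The mean of FAM133B with sgRNA-B lay below the level of silent genes, so the size of its difference is uncertain.

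Probe sets without a gene name, outside the comparisons of genes, also changed in limma: 27 of 799 with sgRNA-A (11 higher, 16 lower), 31 with sgRNA-B (15 higher, 16 lower) and 1 between the guides. These are 3.379% and 3.88% against control, beside 2.19% and 3.08% of the named probe sets.

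Probe sets of the 14q32 locus showed no rise although RT-qPCR had found its microRNAs raised, per the labels. For most of them a level too low to be read is a candidate explanation: 88.2% of the locus probe sets lay at or below the level of silent genes. The 12 above it had a median log2 fold change of 0.044 with sgRNA-A and -0.066 with sgRNA-B, and 0 changed in limma (0 and 1 at an unadjusted p below 0.05), so that the level leaves these unexplained. The locus median of the mean contrast stayed at or below 0.000702 whichever array was left out, but over probe sets at that level it cannot decide whether 1 array hid a rise. Whether these probe sets respond to mature microRNAs at all was not tested. The arrays thus speak neither for nor against the rise that RT-qPCR had found.

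G2/M and mitosis genes were higher in both activated lines, which share their control arrays. Of the 84 splits of the 9 arrays into 6 and 3, 1, the real one, gave a list median as large (0.187). The highest other was 0.113, which argues against a chance division of the arrays. Whether the 3 control cultures were low together cannot be told from these splits, as no other controls were measured. Without any 1 array the median was at least 0.15 (0.152), so that no single array carried it. A larger share of cycling cells in every phase is argued against by the DNA replication genes, whose median stayed at -0.024 or lower without any 1 array. A different share of cells in G2 and M, a difference between cultures at harvest or a property of the clones may each remain, and these were not tested.

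In the order of the 13794 genes above the level of silent genes, which skips the others, runs of 20 had means beyond shuffled orders, though few of their genes changed: from TOM1 to CYTH4 with sgRNA-A (mean log2 fold change 0.23, 19 above 0 and 4 changed; permutation p = 0.004), from MASP2 to PRAMEF9 with sgRNA-B (mean 0.21, 15 above 0 and 2 changed; permutation p = 0.014) and from SNORD116-1 to PDCD6IPP2 between the guides (mean -0.17, 16 below 0 and 0 changed; permutation p = 0.020). Between the guides a run of zinc finger genes from ZNF14 to ZNF208 (mean -0.17, 17 below 0) also passed the limit set by shuffled orders, and its causes were not tested. Without its most changed gene, no run tested for this stood beyond shuffled orders. This was judged by the largest mean over 20 genes that still held a large part of the run. Its permutation p was 0.906 without MB, 0.926 without FBXO2 and 0.388 without SNORD116-30. For each run this mean kept a size of 0.14, so whether a single gene carries all of a run is not decided. With neighbouring family members averaged, the largest such mean over the run from SNORD116-1 to PDCD6IPP2 fell to a size of 0.021 (permutation p = 1.000). Copies that share probes or regulation could thus carry that run. The run of sgRNA-A kept its mean of 0.23 (permutation p = 0.003). No neighbours in it share a symbol stem, so the averaging could not alter it and decides nothing there. That of sgRNA-B kept 0.17 (permutation p = 0.098), which leaves a part of gene families open. A change of copy number or chromatin over a segment in 1 clone cannot be told apart from a local effect on these genes, since no copy number was measured.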

How the results depend on the processing

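Every alternative here was planned before the data were examined, and none was added later. The counts of changed genes with sgRNA-A, with sgRNA-B, between the guides, for the mean of the guides and shared by both (522, 735, 25, 855 and 298) stayed within 1.5 times under array weights, robust variances, no variance trend, median centring, repeated quantile normalization, other probe set rules and removal of the dimmest 30% of genes. Without 1 array they were 223 to 435, 353 to 735, 6 to 30, 405 to 767 and 137 to 253, with fewer samples behind each. An unmoderated t statistic gave 115, 227, 0, 351 and 77, with 2287 genes at an unadjusted p below 0.05 between the guides; it borrows no spread from other genes. An adjusted p of 0.01 gave 172, 283, 8, 348 and 102, and a 2-fold minimum 7, 6, 3, 3 and 3, since both are stricter. Removing the dimmest 50% raised sgRNA-A to 788, the guide comparison to 39 and the shared genes to 466, with fewer genes tested. The fit of sgRNA-A and control alone called 321, with fewer samples in the estimate of the spread.

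Shifted lists with sgRNA-A, with sgRNA-B, between the guides and for the mean (11, 6, 4 and 9) numbered 5 to 11, 5 to 7, 3 to 5 and 5 to 12 without 1 array. They numbered 2, 2, 1 and 1 with an estimated correlation and 4, 2, 2 and 5 with camera on ranks. With fry they were 14 for sgRNA-B and 16 for the mean, and without the dimmest 30% of genes 7 for sgRNA-A. The cause was not tested for these list counts. No called gene or list reversed its direction under any alternative that was run. Of named genes called at the outset, 45 of 89 with sgRNA-A, 65 of 108 with sgRNA-B and 6 of 18 between the guides kept their calls without any 1 array, and of lists 5 of 11, 5 of 6 and 2 of 4. The planned test of microRNA seed sites was not run. Signal over background limits the dim genes: 13812 of 23931 genes had a mean above the level of silent genes.

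With the replicate number as a block, the counts were 465, 684, 34, 798 and 281 genes and 10, 6, 5 and 7 lists. The numbers gave little sign of pairing: the 9 correlations between arrays of the same number ranged from -0.15 to 0.14, with 1 over 0.1. In 5 of these 9 pairs the best match had the same number. All 5 were pairs of a control array with an array of a guide, so a weak pairing with the controls stays open.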

Other observations

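The splits of the arrays were set before the results were seen, and the genes below follow the rule for named genes.

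Among lists that did not shift as a whole, amino acid genes moved in opposing ways. With sgRNA-B, 6 of 21 amino acid response genes changed: the serine synthesis enzymes PHGDH (log2 fold change 0.49), PSAT1 (0.29) and SHMT2 (0.32), which makes glycine from serine, rose, while the subunits of an amino acid transporter, SLC7A5 (-0.40) and SLC3A2 (-0.29), fell. With sgRNA-A 3 changed: PSAT1 rose by 0.30 and SHMT2 by 0.32, and SLC7A5 fell by 0.27; SHMT2 was not called without control replicate 1 (adjusted p = 0.0525, limma). Among integrins and laminins (24 genes, 1 rose and 2 fell with sgRNA-A, 2 rose and 3 fell with sgRNA-B), LAMB1 rose by 0.29 and 0.25, and LAMB3 fell by 0.45 with sgRNA-B. Of 24 YAP targets, 3 rose and 3 fell with sgRNA-A, and 1 rose and 3 fell with sgRNA-B. Among them AXL rose by 0.39 with sgRNA-A, and DOCK5 (-0.39) and the tissue factor gene F3 (-0.27) fell with sgRNA-B. These differences were not particular to 1 guide. All sgRNA-B arrays also lay above the control arrays for AXL, and all sgRNA-A arrays below them for DOCK5 and F3. Aldehyde and xenobiotic genes (21, of which 2 fell with sgRNA-A, and 2 rose and 2 fell with sgRNA-B) included the glutathione transferase GSTP1, which fell by 0.60 with sgRNA-A, and CYP24A1 (0.55) and ALDH1A3 (0.34), which rose with sgRNA-B. The cytokine gene list (1 rose and 1 fell of 27 with sgRNA-A, 2 and 2 with sgRNA-B) held TNFAIP2, which rose by 0.38 and 0.35, and the prostaglandin synthase PTGS2, which fell by 0.63 with sgRNA-A, a call lost without sgRNA-A replicate 3 (0.0605) or control replicate 1 (0.0699). HMOX1 rose by 0.45 with sgRNA-A among NRF2 targets, of which 2 fell there and 1 of 20 fell with sgRNA-B. GDF15 fell by 0.55 with sgRNA-A among p53 targets, of which 1 of 26 rose with sgRNA-B. For GSTP1, PTGS2 and GDF15 all sgRNA-B arrays also lay below the control arrays. All sgRNA-A arrays lay above them for CYP24A1 and ALDH1A3. For HMOX1 the sgRNA-B arrays overlapped the control arrays.

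In the other lists few members changed. Among other imprinted genes (2 and 4 of 24 fell), PEG10 fell by 0.23 with sgRNA-A, a call lost without control replicate 1 (adjusted p = 0.0525, limma). Matrix protease genes (1 of 24 fell with sgRNA-A, 1 rose and 2 fell with sgRNA-B) included PLAU, which rose by 0.22 with sgRNA-B, and ADAM9, which fell by 0.20. Alveolar and club cell genes (1 of 24 fell with sgRNA-A, 1 rose and 1 fell with sgRNA-B) included MUC1, which rose by 0.42 with sgRNA-B. Antigen presentation genes (1 and 2 of 21 rose) held TAPBP, which rose by 0.43 with sgRNA-B. SOX9, among Wnt targets (1 and 2 of 21 rose), rose by 0.29 with sgRNA-B. For PEG10, PLAU, ADAM9, TAPBP and SOX9 all arrays of the other guide also lay on the same side of the control arrays. For MUC1 the sgRNA-A arrays overlapped the control arrays. Members changed numbered 1 and 2 of 23 for the unfolded protein response, 1 and 2 of 22 for TGF-beta targets, and 1 and 1 of 17 for glycolysis. For microRNA pathway genes they were 0 and 2 of 21, with 2 at an unadjusted p below 0.05 in limma with sgRNA-A, and for genes flanking the locus 0 and 1 of 30, with 2. For apoptosis regulators 0 and 0 of 22 changed, with 7 and 4 at an unadjusted p below 0.05 in limma. Markers of other cells changed little: haematopoietic genes 1 and 1 of 17; cancer-testis genes 0 and 1 of 22, with 3 at an unadjusted p below 0.05 with sgRNA-A. In limma, 0 and 0 changed of 19 neuroendocrine genes (unadjusted 2 and 4), of 15 fibroblast genes (unadjusted 1 and 0) and of 14 endothelial genes (unadjusted 1 and 1). In all, 25 of the 38 lists shifted in none of the comparisons of 2 groups, and the lowest camera adjusted p among them was 0.0658.

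Other splits of the same arrays were compared with the real ones, by limma fits of 2 groups. For the mean of the guides, 1 of 84 splits, the real one, gave as many genes (654, highest other 26). As many shifted lists were also found in 1 of 84 (9, highest other 6). This argues against a chance division of the arrays, but other splits mix the groups, which widens the spread within them. The counts cannot separate an effect of the guides from a property of the clones or of the 3 control cultures. Shared calls were as many in 1 of 100 splits into 3 groups, the real one (298, highest other 7). Splits that mix the groups leave few calls to share, so this cannot decide how much of the overlap comes from the shared controls. Splits of 6 arrays number 10, too few for a share under 0.05: the real and highest other counts of genes were 321 and 0 with sgRNA-A (unadjusted p below 0.05 at 2922 and 1312), 653 and 0 with sgRNA-B (unadjusted 3688 and 1231) and 26 and 1 between the guides. Counts of lists were 9 and 3, 6 and 2, and 4 and 1, and 1 split of 10 reached the real value in each.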
